A study of Rattus norvegicus with 16 samples.

How the data were processed

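Total RNA from rat dentate gyrus, the part of the hippocampal formation that receives the main cortical input, was measured on 16 Affymetrix RGU34A arrays, a single-colour rat expression array. The arrays fall into 7 groups per the labels: naive (3 arrays), 0 h (2), 2 h (2), 3 h (2), 6 h (3), 12 h (2) and 24 h (2). Every label, the naive ones included, says that the samples are from passive avoidance trained rats. The naive group is taken here as untrained, and the other groups are called trained. The labels do not say that the hours count from training. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

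The deposited values are linear intensity summaries, with 1 value per probe set and array. The software, background correction and scaling behind them are not given in the sources used here. The table held 8799 probe sets, of which 59 were controls. The 2% trimmed mean of the other 8740 probe sets ranged from 33.3 to 170 between arrays, a 5.11-fold range, so the arrays had not been brought to a common scale before deposit.

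Each array was scaled to a common 2% trimmed mean of 105. Values under the pooled 20th percentile (5.05) were set to it, and log2 was taken. A probe set was tested if it exceeded the pooled 40th percentile (16.9) on at least 2 of the 16 arrays, which left 6220 probe sets. Where all arrays of a group lie at that lowest level, a fold or difference that includes the group is given as a lower bound. The number of arrays limits the precision, and no depth in the sense of read counts applies.

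Genes were named through the platform annotation, with symbols updated by gene identifier; 6994 annotation rows matched. Of the 8740 probe sets, 7006 carried 1 symbol, 308 carried several, and 1426 were not listed and are unnamed here. The tested probe sets with 1 symbol covered 3678 genes, 1091 of them with more than 1 probe set. Where the probe sets of a named gene differ in direction or by over 1 on the log2 scale, their values are given.

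Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend) over all 7 groups, which share 1 estimate of the spread. The comparisons were each hour against naive, the equal-weight mean of the 6 trained groups against naive, an F test over the 7 groups, and an F test over the 6 trained times. P-values were adjusted by the Benjamini-Hochberg method at 0.05. The comparisons against naive share the same 3 naive arrays, so their results are not independent.

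Fixed gene lists were tested with limma's camera at a preset correlation of 0.01, using for each gene the probe set with the highest mean, and adjusted over the lists within a comparison. The 15 functional lists were immediate early genes, trophic factors and neuropeptides, glutamate receptors with their scaffolds, the GABA system, synaptic vesicle release, cell adhesion and matrix, cytoskeleton and neurite growth, calcium, cyclic AMP and MAP kinase signalling, glucocorticoid responsive genes, heat shock proteins and chaperones, ribosomal proteins, oxidative phosphorylation, proteasome and ubiquitin, glycolysis, and voltage-gated ion channels. The 10 marker lists were dentate granule neuron, pyramidal neuron, interneuron, thalamus, astrocyte, oligodendrocyte, microglia, endothelium and mural cells, choroid plexus with ependyma and meninges, and blood cells. The array scores described below covered all 25 lists. Camera was not run on lists with under 5 measured genes, which left 23. The same test was run with the correlation estimated from the data. A score per array, the mean over a list's genes of the deviation from each gene's mean over all arrays, was tested by permutation (100000 permutations; for naive against trained, all 560 splits).

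The design, preprocessing, gene lists, alternatives and naming rule were fixed before the data were examined. The rule took, for each comparison, the probe sets past the threshold with the largest change (up to 25 for the F tests and for trained against naive, up to 20 per hour). Where fewer passed, places were filled by the smallest unadjusted p to 10 in all. Any member of a fixed list could also be named. Alternatives covered the normalization, the lowest level, the filter, the variance model, array weights, a replicate block, fits of only the groups compared, and leaving out each array. The settings chosen after seeing the data were 1 probe set per gene, the beta-actin 3'/5' ratio as a covariate, the Ttr level as a covariate (with Ttr left out of the genes fitted), Ttr left out with no covariate, and leaving out both arrays least correlated with the rest.

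The models were tested on simulated arrays of 6220 probe sets with the measured means and spreads, and noise drawn independently for each probe set. Noise shared between probe sets was not simulated, so the shares below may be optimistic for the real arrays. At 6 h, with 3 arrays, 36 of 100 probe sets changed 2-fold and 84 of 100 changed 4-fold were recovered. At 24 h, with 2 arrays, 23 of 100 and 73 of 100 were recovered. Of the probe sets called, 7 of 127 at 6 h and 5 of 101 at 24 h had not been changed. Figures were drawn with matplotlib 3.10.9.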

Results

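Passive avoidance is a learning task in which an animal withholds a response that was followed by an aversive event. Transcript levels in the dentate gyrus of naive rats (3 arrays) were set against those of trained rats in groups labelled 0 h (2 arrays), 2 h (2), 3 h (2), 6 h (3), 12 h (2) and 24 h (2). The trimmed mean intensity before scaling was lowest on 12 h replicate 1 (33.3) and highest on 24 h replicate 2 (170). Correlations between arrays ranged from 0.908 to 0.973.

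2 measures varied widely between arrays. Ttr, which encodes transthyretin and is very abundant in choroid plexus, averaged 11.53 on the log2 scale in naive arrays and spanned a 93.9-fold range over all arrays. Within the 0 h group it was 11.27 on replicate 1 and 6.65 on replicate 2, and both 24 h arrays were low (6.31 and 6.13). The ratio of the 3' to the 5' beta-actin control probe set, which rises when RNA or its labelled copies are shorter, was 1.49 to 1.70 in naive arrays. It lay above every naive array in 12 of 13 trained arrays, which ranged from 1.51 to 2.80. The corresponding Gapdh ratio was above every naive array in 8 of 13 trained arrays. Ttr was at or above the lowest naive array in only 3 trained arrays. Used as covariates below, Ttr and the actin ratio therefore overlap with the comparisons against naive. A call lost under either can come from a larger error, and does not show that tissue or RNA quality caused the change.

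**Figure D1:**
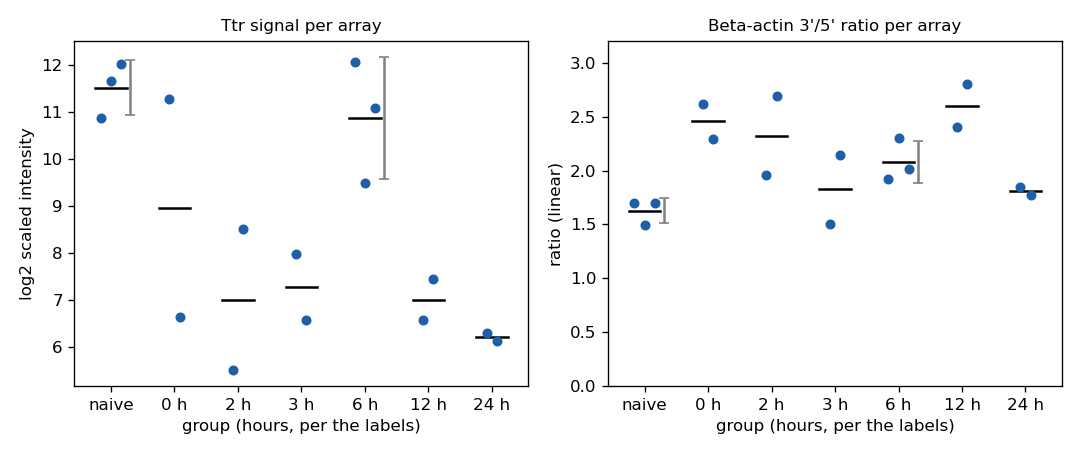
Ttr signal (log2 scaled intensity, left) and beta-actin 3'/5' ratio (linear, right) for each array by group; points are arrays, black lines group means, and grey bars SD for groups of 3. Ttr was 11.27 and 6.65 on the 0 h arrays and 6.31 and 6.13 on the 24 h arrays.

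Over the 7 groups, the probe sets with the smallest p included Bckdha (a subunit of branched-chain keto acid dehydrogenase), Hnrnpu (a nuclear RNA-binding protein), Ttr, Enpp2 (autotaxin, also abundant in choroid plexus), the kinesin Kif3c and the myelin gene Mal. None of the 6220 probe sets passed limma's F test after adjustment, and 640 had an unadjusted p under 0.05 where 311 are expected by chance. The smallest adjusted p was 0.179. Among the 6 trained times none passed, 670 had an unadjusted p under 0.05, and Hnrnpu, Bckdha, Adarb1 and Lcat led with adjusted p of 0.198 to 0.226. Without 6 h replicate 3, the counts past the threshold were 8 over the 7 groups and 7 over the trained times, and no other left-out array gave more than 2.

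In all trained groups against naive, the choroid plexus genes Enpp2 and Ttr were among the probe sets with the smallest p. Enpp2 was 5.56-fold lower (log2 difference -2.48, SE 0.46) and below the naive mean in 13 of 13 trained arrays. Ttr was 9.70-fold lower (-3.28, SE 0.65) and below the naive mean in 12 of 13. Outside the choroid plexus list, Scgb1c1 was 6.72-fold lower (-2.75, SE 0.57). The anion exchanger Slc4a2 was at least 6.51-fold lower (-2.70, SE 0.54, and -0.82 by a second probe set). By the first probe set Slc4a2 lay at the lowest level on 9 of 13 trained arrays, among them all of the 2 h, 12 h and 24 h groups. Without naive replicate 1, Scgb1c1 was -3.75 and Slc4a2 lower by at least 3.67, and both passed. Each of the 4 had a limma adjusted p of 0.181, and none of the 6220 probe sets passed; 333 had an unadjusted p under 0.05. The choroid plexus list fell (9 of 15 genes below naive, median log2 difference -0.31, mean -0.83, camera adjusted p = 1.11e-06; adjusted p = 0.17 with an estimated correlation), and 6 of its genes passed when adjusted over the list alone, among them Sostdc1 (-2.23, SE 0.50) and Igfbp2 (-1.23, SE 0.28). The list score was -0.08, 1.17 and 0.85 on naive replicates 1 to 3, and 5 of 13 trained arrays lay above naive replicate 1; without naive replicate 2 the list mean was -0.53 (adjusted p = 0.0302). It was -1.29 with the filter at the 60th percentile, and with Ttr left out of the list -0.65 (4.3e-05). For these 14 genes it was -0.22 with the Ttr level as a covariate, where the call was lost (0.566). Without naive replicate 1, 17 probe sets passed, all lower and 8 of them from the choroid plexus list; without 0 h replicate 1, 2 passed.

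7 other lists differed between trained and naive arrays, with smaller shifts. Ribosomal protein genes rose (38 of 42 above naive, mean 0.17, camera adjusted p = 9.98e-10; 0.17 with an estimated correlation), with Rps3 at 0.39 (SE 0.13). Oxidative phosphorylation genes rose (39 of 55, mean 0.08, adjusted p = 0.00202; 0.329 with an estimated correlation), as did trophic factors and neuropeptides (23 of 30, mean 0.17, adjusted p = 0.00594; 0.122 with an estimated correlation), where thyrotropin-releasing hormone, Trh, was 0.53 (SE 0.20). Oligodendrocyte genes fell (11 of 13 below naive, mean -0.27, adjusted p = 1.98e-05; 0.275 with an estimated correlation). Glutamate receptor genes fell (24 of 30, mean -0.15, adjusted p = 0.0161; 0.429 with an estimated correlation), as did synaptic vesicle genes (25 of 35, mean -0.12, adjusted p = 0.0341; 0.302 with an estimated correlation) and adhesion and matrix genes (33 of 50, mean -0.13, adjusted p = 0.0481; 0.322 with an estimated correlation). Only Cox8b, of these 7 lists, passed when adjusted over its list alone (-2.07, SE 0.45), and it went against the rise of the oxidative phosphorylation list. With the beta-actin 3'/5' ratio as a covariate the calls were lost for ribosomal proteins (mean 0.07, adjusted p = 0.0679), oxidative phosphorylation (0.08, 0.443) and trophic factors (0.16, 0.54), and the glutamate receptor, synaptic vesicle and adhesion means turned to 0.11 (0.819), 0.0094 (0.634) and 0.022 (0.77). With the Ttr level as a covariate the ribosomal mean was 0.12 (0.00592). The other 6 calls were lost: oxidative phosphorylation 0.0050 (0.98), trophic factors 0.18 (0.153), oligodendrocytes -0.09 (0.497), glutamate receptors -0.09 (0.373), adhesion -0.0058 (0.98), and synaptic vesicles, which turned to 0.053 (0.98). The oxidative phosphorylation mean was 0.05 with quantile normalization (call lost, 0.12), array weights (0.044) or averaged probe sets (0.0148). The adhesion call was also lost with array weights (0.0808), median centring (0.0522), a filter at the 60th percentile (0.135) or averaged probe sets (0.0916).

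5 of these 7 calls were lost when single arrays were left out. The oxidative phosphorylation call was lost without naive replicate 2 (mean 0.08, adjusted p = 0.0844) or naive replicate 3 (0.02, 0.465), with a mean of 0.13 without naive replicate 1, and the trophic factor call without naive replicate 2 (0.16, 0.125). The glutamate receptor call was lost without naive replicate 1 (-0.07, 0.589), 3 h replicate 2 (-0.11, 0.0672) or 12 h replicate 2 (-0.14, 0.074), and its mean was -0.24 without naive replicate 3. The synaptic vesicle call was lost without naive replicate 1 (-0.14, 0.0927), 2 (-0.10, 0.0708) or 3 (-0.11, 0.155), 0 h replicate 2 (-0.10, 0.0785), 2 h replicate 1 (-0.11, 0.0785), 3 h replicate 2 (-0.09, 0.0672), 6 h replicate 3 (-0.12, 0.055) or 12 h replicate 2 (-0.09, 0.144). The adhesion call was lost without naive replicate 2 (-0.09, 0.144) or 3 (-0.14, 0.155), 0 h replicate 2 (-0.12, 0.0945), 2 h replicate 1 (-0.14, 0.0684), 3 h replicate 2 (-0.11, 0.0672), 6 h replicate 2 (-0.12, 0.053) or 3 (-0.13, 0.0673), 12 h replicate 2 (-0.11, 0.17) or 24 h replicate 2 (-0.12, 0.0727), and its mean was -0.20 without naive replicate 1. The ribosomal and oligodendrocyte calls held without each array in turn.

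At 0 h, heat shock protein and chaperone genes rose as a list (27 of 33 above naive, mean log2 difference 0.18, camera adjusted p = 0.00189; 0.356 with an estimated correlation). Cryab was 0.65 (SE 0.27) and the mitochondrial chaperone Hspd1 0.44 (SE 0.19). Oxidative phosphorylation genes rose (39 of 55, mean 0.13, adjusted p = 0.00189; 0.432 with an estimated correlation), and choroid plexus genes fell (12 of 15 below naive, mean -0.77, adjusted p = 0.00189; 0.427 with an estimated correlation). No member of these lists passed when adjusted over its list alone. The lowest p of the probe sets with 1 gene symbol was that of Ctsd, a lysosomal protease (-0.98, SE 0.21, limma adjusted p = 0.793, and -0.65 by a second probe set). None of 6220 probe sets passed limma's test, and 311 had an unadjusted p under 0.05. The actin ratio was 2.62 and 2.30 on these arrays, above all naive ones (at most 1.70), so as a covariate it overlaps with this comparison. With it the heat shock (mean 0.24, adjusted p = 0.0786) and oxidative phosphorylation calls (0.13, 0.338) were lost, while the means without it were 0.18 and 0.13. With the Ttr level the oxidative phosphorylation (0.08, 0.269) and choroid plexus calls (-0.36, 0.269) were lost. The choroid plexus mean without that covariate was -0.66 for the 14 genes other than Ttr. Averaged probe sets ended the heat shock (0.07, 0.148) and oxidative phosphorylation calls (0.03, 0.192), and quantile normalization the latter (0.08, 0.142). The heat shock call was lost without naive replicate 2 (0.13, 0.0793), the oxidative phosphorylation call without 0 h replicate 1 (0.09, 0.0725) or naive replicate 3 (0.07, 0.243), and the choroid plexus call without 0 h replicate 2 (-0.49, 0.122), naive replicate 2 (-0.48, 0.0838) or naive replicate 3 (-0.63, 0.108).

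At 2 h, 1 probe set passed: Bckdha fell 4.50-fold (-2.17, SE 0.34, limma adjusted p = 0.0457, below the naive mean in 2 of 2 arrays). Its log2 difference ranged from -2.88 to -1.46 over the alternatives. A second Bckdha probe set was -0.49, and the call was lost in 21 of 31 alternatives, including leaving out any array other than naive replicate 1 or 2 h replicate 2. 477 probe sets had an unadjusted p under 0.05. Among them were the protease Furin (-1.73, SE 0.34), Nnat (-1.16, SE 0.26), Trh (1.24, SE 0.28) and Ttr (-5.19, SE 1.16), each with an adjusted p of 0.236. Ttr was 36.5-fold lower by this probe set, and averaged 7.58 against 11.41 in naive by a second. The choroid plexus list was not called at 2 h. Second probe sets went the other way for Furin (0.29) and Trh (-0.44). Ribosomal protein genes rose (40 of 42, mean 0.34, camera adjusted p = 1.77e-09; 0.417 with an estimated correlation), with Rps3 at 0.66 (SE 0.18) and Rpl7a at 0.72 (SE 0.21), though none passed when adjusted over the list alone. Oligodendrocyte genes fell (12 of 13, mean -0.44, adjusted p = 3.07e-05; 0.461 with an estimated correlation), and Mal (-0.95, SE 0.23) passed when adjusted over the list alone. The list score was -0.50 on 2 h replicate 1 and 0.04 on replicate 2; without replicate 1 the mean was -0.17 (adjusted p = 0.58), and without replicate 2 -0.71. With the Ttr level as a covariate it was -0.23 and the call was lost (0.246); with the actin ratio the ribosomal mean was 0.22 (0.0116). Without naive replicate 1, 11 probe sets passed; without 2 h replicate 1, 3 passed.

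At 3 h, Enpp2 was 15.2-fold lower (-3.92, SE 0.65, limma adjusted p = 0.0911), and 6.14-fold (-2.62) by a second probe set. The alternatives gave -4.90 to -2.58 for the first Enpp2 probe set and -3.63 to -1.28 for the second. Hnrnpu was 3.28-fold lower (-1.71, SE 0.30, adjusted p = 0.0931), while a second Hnrnpu probe set was -0.20. None of 6220 probe sets passed limma's test and 268 had an unadjusted p under 0.05. The choroid plexus list fell (9 of 15 genes below naive, median -0.13, mean -0.90, camera adjusted p = 0.0021; 0.439 with an estimated correlation), with 4 genes past when adjusted over the list alone. The GABA list fell (15 of 20 below naive, mean -0.40, adjusted p = 0.0021; 0.113 with an estimated correlation), and Gad2, which makes GABA (-1.45, SE 0.40), Gabrg1 (-1.23, SE 0.36) and Gabrr1 (-1.11, SE 0.36) passed when adjusted over the list alone. Glutamate receptor genes fell (25 of 30, mean -0.25, adjusted p = 0.0336; 0.53 with an estimated correlation). Ribosomal protein genes rose (35 of 42, mean 0.12, adjusted p = 4.2e-07; 0.396 with an estimated correlation), although Rpl30, at the lowest level on both arrays, was lower by at least 2.72 (SE 0.82), and oxidative phosphorylation genes rose (46 of 55, mean 0.10, adjusted p = 6.2e-05; 0.407 with an estimated correlation). No glutamate receptor or ribosomal gene passed when adjusted over its list alone, and of the oxidative phosphorylation genes Cox8b did, against the list's direction (-3.11, SE 0.64). The glutamate receptor score was 0.17 on 3 h replicate 1 and -0.40 on replicate 2 (naive mean 0.13), and the GABA score -0.07 and -0.47. Without 3 h replicate 2 no call of these lists other than the choroid plexus one held: the mean was 0.03 for glutamate receptors (adjusted p = 0.994), -0.20 for GABA (0.123), -0.0034 for ribosomal proteins (0.131) and 0.07 for oxidative phosphorylation (0.0624). Without 3 h replicate 1 the glutamate receptor mean was -0.54, the ribosomal mean 0.24, and the choroid plexus call was lost (-0.90, 0.055), as it was without naive replicate 2 (-0.62, 0.155). The glutamate receptor call was also lost without naive replicate 1 (-0.17, 0.445) or 2 (-0.25, 0.0521), and the oxidative phosphorylation mean was 0.15 without naive replicate 1 and 0.04 without naive replicate 3. A covariate of the Ttr level ended the calls for choroid plexus (-0.17, 0.853; -0.68 without it for the 14 genes other than Ttr), GABA (-0.24, 0.373), glutamate receptors (-0.18, 0.373) and oxidative phosphorylation (0.013, 0.539), and the ribosomal mean was 0.05 (0.0136). The glutamate receptor call was also lost with the actin ratio (-0.16, 0.161) or quantile normalization (-0.12, 0.0564). Median centring, which kept the calls, gave -0.22 for GABA, -0.08 for glutamate receptors, 0.28 for oxidative phosphorylation and 0.30 for ribosomal proteins, and the filter at the 60th percentile gave -1.53 for choroid plexus. Without naive replicate 1, 9 probe sets passed, without 3 h replicate 2, 4, and without 0 h replicate 1 or 3 h replicate 1, 2 each.

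At 6 h, ribosomal protein genes rose (38 of 42, mean 0.32, camera adjusted p = 4.54e-12; 0.187 with an estimated correlation), and Rpl35 (0.70, SE 0.19) and Rps23 (0.60, SE 0.17) were among 3 that passed when adjusted over the list alone. Oxidative phosphorylation genes rose (42 of 55, mean 0.15, adjusted p = 6.4e-05; 0.307 with an estimated correlation), and the only member past over the list alone, Cox4i2, was lower (-1.24, SE 0.29). Synaptic vesicle genes fell (24 of 35, mean -0.26, adjusted p = 0.00106; 0.187 with an estimated correlation), with Rab3a at -0.63 (SE 0.18) and the synapsin Syn1 at -0.63 (SE 0.21), neither past over the list alone. Glutamate receptor genes fell (22 of 30, mean -0.29, adjusted p = 0.00338; 0.447 with an estimated correlation), none past over the list alone. Of single probe sets, Kif3c (-1.56, SE 0.30; -0.09 by a second), 2 for the amyloid precursor App (-1.32, SE 0.26, and -1.13, SE 0.23) and the vesicle protein Sv2b (-1.33, SE 0.27; 0.18 by a second) had adjusted p of 0.234. None of 6220 passed limma's test, and 585 had an unadjusted p under 0.05. With the actin ratio as a covariate the glutamate receptor mean was -0.05 and its call was lost (adjusted p = 0.378), and the synaptic vesicle mean was -0.15 (0.0208). The oxidative phosphorylation mean was 0.23 with median centring and 0.09 with quantile normalization (0.0494) or averaged probe sets. The glutamate receptor call was lost without naive replicate 1 (-0.20, 0.133) and the oxidative phosphorylation call without 6 h replicate 3 (0.10, 0.0579), with a mean of 0.09 without naive replicate 3. Without 6 h replicate 3, 29 passed, and without naive replicate 1, 1.

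At 12 h, trophic factor and neuropeptide genes rose as a list (23 of 30 above naive, mean 0.36, camera adjusted p = 0.0098; 0.0989 with an estimated correlation), and none passed when adjusted over the list alone. Trh was 0.73 (SE 0.28) and the neurotrophin receptor Ntrk2 0.67 (SE 0.28). Choroid plexus genes fell (11 of 15, mean -0.97, adjusted p = 5.48e-05; 0.431 with an estimated correlation), and Ttr, Igfbp2 (-1.70, SE 0.39), Sostdc1 and Enpp2 passed when adjusted over the list alone. The prolactin receptor Prlr lay at the lowest level on both arrays by 1 probe set, at least 7.55-fold lower than naive (adjusted p = 0.199), while the other 2 probe sets were -0.92 and -0.0017. None of 6220 probe sets passed limma's test, and 631 had an unadjusted p under 0.05. Those with 1 gene symbol were led by the endophilin Sh3gl2 (-2.02, SE 0.41) and Cops7a (-1.19, SE 0.24, and -0.51 by a second probe set). Each had an adjusted p of 0.199. Sh3gl2 ranged from -2.85 to -0.92 over the alternatives. 12 h replicate 1 was the dimmest array, and the actin ratio was 2.40 and 2.80. With this ratio as a covariate the trophic factor call was lost (mean 0.36, adjusted p = 0.425), as it was with the Ttr level (0.38, 0.1), no filter (0.33, 0.113), a filter at the 60th percentile (0.31, 0.108) or both least correlated arrays left out (0.28, 0.156). The choroid plexus call was lost too with the Ttr level (-0.22, 0.59; -0.76 without it for the 14 genes other than Ttr). The trophic factor call was lost without 12 h replicate 1 (0.31, 0.121), 6 h replicate 3 (0.27, 0.0818) or naive replicate 2 (0.36, 0.0557). Without 12 h replicate 2, 23 probe sets passed, without naive replicate 1, 5, without 12 h replicate 1, 3, and without 6 h replicate 3, 2.

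At 24 h, oligodendrocyte genes fell (13 of 13 below naive, mean -0.73, camera adjusted p = 1.85e-15; 0.0688 with an estimated correlation). Of these, 7 passed when adjusted over the list alone, including the myelin genes Mal (-1.26, SE 0.23), Mag (-0.95, SE 0.23; -0.54 by a second probe set), Mog (-1.14, SE 0.33), Cnp (-0.79, SE 0.23) and Mbp (-0.83, SE 0.28). Choroid plexus genes fell (14 of 15, mean -1.39, adjusted p = 1.66e-09; 0.0688 with an estimated correlation), with 7 past over the list alone, such as Ttr (-5.21, SE 0.91) and Igf2 (-2.04, SE 0.56; -0.04, -0.13 and -0.28 by 3 other probe sets). Endothelial and mural genes fell (11 of 16, mean -0.37, adjusted p = 0.0122; 0.0688 with an estimated correlation), and ribosomal protein (31 of 42, mean 0.08, adjusted p = 0.013; 0.467 with an estimated correlation) and oxidative phosphorylation genes (41 of 55, mean 0.09, adjusted p = 0.0238; 0.467 with an estimated correlation) rose, with no gene of these 3 lists past over its list alone. None of 6220 probe sets passed limma's test, and 276 had an unadjusted p under 0.05. Of those with 1 gene symbol, Ttr, Mal and Enpp2 had the smallest adjusted p, 0.0835. With the Ttr level as a covariate the oligodendrocyte mean was -0.48 (adjusted p = 0.00119), and the other calls were lost: choroid plexus -0.49 (0.5; -1.12 without the covariate for the 14 genes other than Ttr), endothelium -0.14 (0.813), oxidative phosphorylation -0.014 (0.954) and ribosomal proteins -0.0033 (0.713). With the actin ratio the ribosomal (0.04, 0.193) and oxidative phosphorylation calls (0.09, 0.154) were lost, as they were with quantile normalization (0.08, 0.0624, and 0.10, 0.121); median centring gave 0.15 and 0.16. Array weights (0.06, 0.0945) or no variance trend (0.09, 0.0519) also ended the oxidative phosphorylation call, and averaged probe sets (-0.27, 0.0687) or no filter (-0.30, 0.0505) the endothelial one. The filter at the 60th percentile gave -2.10 for choroid plexus. The ribosomal call was lost without 24 h replicate 2 (-0.0044, adjusted p = 0.854) or naive replicate 2 (0.05, 0.203), and its mean was 0.17 without 24 h replicate 1. The endothelial call was lost without 24 h replicate 1 (-0.36, 0.0582). The oxidative phosphorylation call was lost without 24 h replicate 1 (0.06, 0.0582) or 2 (0.13, 0.138), or naive replicate 2 (0.10, 0.2) or 3 (0.04, 0.289), with a mean of 0.14 without naive replicate 1. Without naive replicate 1, 12 passed, without 2 h replicate 1 or 2 h replicate 2, 4 each, without 0 h replicate 1 or 0 h replicate 2, 2 each, and without 24 h replicate 2, 1.

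**Figure D2:**
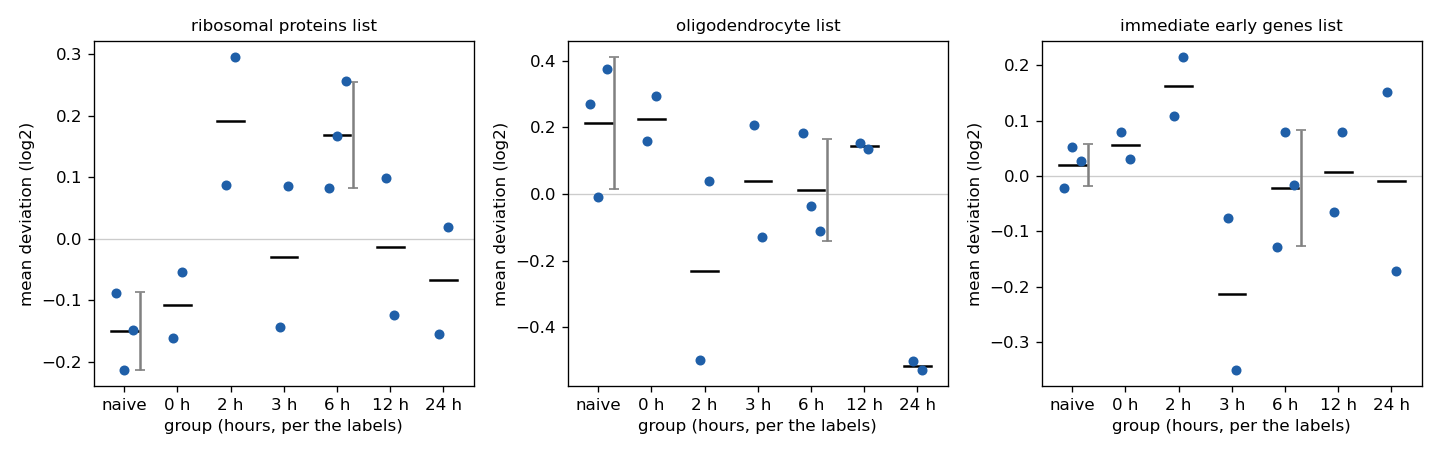
Mean deviation (log2) of the ribosomal protein, oligodendrocyte and immediate early gene lists for each array by group; points are arrays, black lines group means, and grey bars SD for groups of 3. The oligodendrocyte score was -0.50 and -0.53 on the 24 h arrays.

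Immediate early genes, which many neurons transcribe soon after activity, were called at no hour. Their smallest camera adjusted p was 0.235, at 3 h. Egr1 was 0.68 (SE 0.30; 0.47, -0.16 and -0.12 by 3 other probe sets) at 0 h, Nr4a3 0.80 (SE 0.32) at 2 h, and Fos 0.21 (SE 0.25; 1.18 by a second probe set) at 2 h, none past when adjusted over the list alone. Klf6 at 3 h was the only member past over the list alone (-2.63, SE 0.65). The smallest adjusted p over the 7 comparisons was 0.118 for glucocorticoid responsive genes, 0.0792 for proteasome and ubiquitin, 0.0883 for blood cells, 0.152 for astrocytes, and 0.191 for voltage-gated ion channels. It was 0.248 for calcium, cyclic AMP and MAP kinase signalling, for pyramidal neurons and for microglia, 0.275 for interneurons, 0.376 for glycolysis and 0.439 for the cytoskeleton. The dentate granule neuron list (4 genes measured) and the thalamus list (3) were too small to test with camera. By permutation of array scores over the 7 groups, their adjusted p was 0.409 and 0.545.

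In all, 29 of 161 list comparisons were called by camera at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0688. With the Ttr level as a covariate, 10 were called. By permutation of array scores, no list differed over the 7 groups after adjustment. The smallest adjusted permutation p was 0.0975, for trophic factors and neuropeptides, the GABA system and glucocorticoid responsive genes. For naive against trained over all 560 splits, no list passed either (smallest adjusted p = 0.446), and the choroid plexus list had an unadjusted exact p of 0.0179.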

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

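Control probe sets were not among the probe sets tested. Their 3'/5' ratio lay above every naive array on 12 of 13 trained arrays for beta-actin and on 8 of 13 for Gapdh. For beta-actin the highest ratio was 2.80, on 12 h replicate 2, and for Gapdh it was 2.04, on 6 h replicate 2, against naive maxima of 1.70 and 1.28.

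In this part, the random regroupings other than that of the hour with the most probe sets, the array brightness tests of the ribosomal list at 6 h and the oligodendrocyte list at 24 h, and the white matter test were set before their results were seen; the other tests were chosen after the result was seen.

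The choroid plexus list was below naive over all trained arrays and at 0, 3, 12 and 24 h. A single level set by training at every hour is argued against by 3 trained arrays with Ttr at or above the lowest naive array, in groups that also held arrays far below it; naive replicate 1 had a list score of -0.08, below 5 trained arrays. Uneven carry-over of choroid plexus during dissection is a candidate explanation. Within groups, the other 14 list genes had a median correlation with Ttr of 0.293, above the 95th percentile of 10000 random lists (0.212). Prlr (-0.26), Dcn (-0.23) and Slc22a6 (-0.11) went the other way. The random lists were matched only on mean signal. The result shows genes that vary together within groups, and cannot tell tissue carry-over from another shared cause. Enpp2 and Ptgds of this list are also expressed by oligodendrocytes. A lower level at 24 h set by training stays open, since 2 arrays against 3 allow no exact permutation p under 0.1, the value obtained.

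The ribosomal protein list was above naive over all trained arrays and at 2, 3, 6 and 24 h. Array brightness as a covariate left 80.8% of the shift at 2 h, 84.1% at 6 h and 80.3% over all trained arrays, with the calls. Over all trained arrays this argues against brightness as the whole cause. Every 2 h array (trimmed mean at most 72.6) and 6 h array (at most 109) was dimmer than every naive array (at least 113). The covariate therefore cannot separate brightness from training at these hours. At 3 h (97.6%) and 24 h (112%) it moved the median gene by under 0.05 and so tested nothing. The beta-actin 3'/5' ratio as a covariate left 42.3% over all trained arrays (mean 0.17, SD over genes 0.26, to 0.07, SD 0.38). That call ended as the shift shrank and the spread over genes grew, so RNA or labelling quality may account for part of it. The ratio lay above every naive array in 12 of 13 trained arrays, so this covariate cannot separate quality from training there. Across the 16 arrays the list score had a Pearson r of 0.41 with the ratio (permutation p = 0.116) and -0.56 with brightness (0.0231). By hour the ratio as a covariate left 63.6% at 2 h, 70.1% at 3 h, 72.6% at 6 h and 52.7% at 24 h. At 24 h (mean 0.08, SD over genes 0.30, to 0.04, SD 0.37) the call was lost too (camera adjusted p = 0.193). These shares by hour decide neither way. A training effect at 6 h cannot be told apart with 3 arrays against 3, where the exact permutation p was 0.1, the smallest possible.

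The oligodendrocyte list was below naive over all trained arrays and at 2 and 24 h, and not at 0 h (mean 0.013, 7 of 13 genes above). Brightness as a covariate left 109% of the shift at 2 h and 108% over all trained arrays. The latter argues against brightness as the whole cause. At 2 h every array was dimmer than every naive array, so that share cannot decide. The actin ratio left 115% at 2 h, 103% at 24 h and 120% over all trained arrays. It lay above every naive array on all 2 h and 24 h arrays and on 12 of 13 trained arrays. It therefore cannot separate RNA quality from training, and its shares do not decide. At 24 h the brightness covariate (99.1% left) moved too little to test, a limit set after its result was seen. Uneven white matter between dissections is a candidate explanation. Within groups, the other 12 list genes had a median correlation with Mbp of 0.413, against a 95th percentile of 0.14 in random lists. That result too shows genes that vary together, and cannot tell uneven white matter from another shared cause. Mbp averaged 11.01 in naive and 10.18 in 24 h arrays, oligodendrocytes are also part of dentate tissue, and the Ttr level as a covariate took the mean from -0.73 to -0.48 at 24 h, from -0.44 to -0.23 at 2 h (adjusted p = 0.246) and from -0.27 to -0.09 over all trained arrays (0.497). An effect of training at 24 h stays open (exact permutation p = 0.1, the smallest possible).

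Random regroupings bear on the counts. As many list calls as the real 29 came from 3 of 100 assignments of the 16 arrays, the real one included (median of the others 15, highest 33). As many probe sets under an unadjusted 0.05 in the F test over 7 groups (640) came from 2 of 100 (median of the others 300, highest 726). Both shares lie under 0.05 before any adjustment over the counts tested in this way. They bear on these totals, not on single calls. If replicates are technical, they cannot exclude chance differences between animals. Chance is not excluded for the 6 trained times (670, reached by 5 of 100, highest other 838). Nor is it for the hour with the most (631, at 12 h, reached by 25 of 100, median of the others 516, highest 1031). The same holds for trained against naive (333, reached by 31 of 100, median of the others 241, highest 1008). For 6 h against naive (585, highest other 888), 2 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.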

How the results depend on the processing

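The settings 1 probe set per gene, both covariates, Ttr left out with no covariate, and both least correlated arrays left out were chosen after seeing the data. Causes were not tested unless given. The number of probe sets past the threshold changed as follows. Quantile normalization gave 0 at 2 h. The lowest level at the 40th percentile gave 2 at 2 h, 11 at 12 h, 4 over the 7 groups and 4 over the trained times. No filter gave 2 at 0 h, 4 at 2 h, 21 at 12 h, 9 over the 7 groups and 10 over the trained times. No variance trend gave 1 at 12 h, 2 over the 7 groups and 2 over the trained times. Without the filter or the trend, Bckdha was not among those past at 2 h. Array weights gave 6 at 24 h. Only the groups compared gave 0 at 2 h, 2 at 3 h, 2 at 12 h and 6 at 24 h. With 1 probe set per gene, 2 passed at 3 h and 3 at 24 h, where fewer tests are adjusted for. The beta-actin ratio as a covariate gave 0 at 2 h and 2 at 3 h. The Ttr level as a covariate gave 0 at 2 h and 10 list calls in place of 29, and an estimated correlation gave 0 list calls. Without both least correlated arrays, 0 passed at 2 h and 10 at 12 h.

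Leaving out each array in turn gave 0 probe sets at 0 h each time, 0 to 11 at 2 h, 0 to 9 at 3 h, 0 to 29 at 6 h, 0 to 23 at 12 h, 0 to 12 at 24 h, 0 to 17 for trained against naive, 0 to 8 over the 7 groups, 0 to 7 over the trained times, and 22 to 33 list calls. Where an hour was left with 1 array, that array is assumed to vary like the other groups.

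The sign of the list mean reversed in 9 list results, none of which passed. With the beta-actin ratio, for trained against naive, the glutamate receptor list was 0.11, the synaptic vesicle list 0.0094 and the adhesion list 0.022. With the Ttr level the oxidative phosphorylation list was -0.014 and the ribosomal list -0.0033 at 24 h, and the synaptic vesicle list 0.053 for trained against naive. Without 3 h replicate 2, at 3 h, the glutamate receptor list was 0.034 and the ribosomal list -0.0034 (-0.54 and 0.24 without replicate 1). Without 24 h replicate 2 the ribosomal list was -0.0044 at 24 h (0.17 without replicate 1). Of the other results, values of named genes kept direction and side of the threshold in 980 alternatives and 1055 fits without 1 array, lost the threshold in 7 and 14, and gained it in 13 and 45. Called lists kept both in 413 and 414 and lost the threshold, in the same direction, in 74 and 47.

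Whether replicate numbers pair the arrays was not settled. The 43 same-number pairs had a median correlation of deviations of 0.025 (12 over 0.1), against -0.024 for 66 others (6 over 0.1). In a group of 2 arrays the deviations from the group mean are mirror images, so these medians are not independent. A replicate block gave 0 probe sets at 2 h in place of 1.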

Other observations

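Across the 16 arrays, the ribosomal protein score fell with array brightness (Pearson r = -0.56, permutation p = 0.0231; Spearman rho = -0.58, permutation p = 0.0221; r = -0.61 without the 2 arrays farthest from the median brightness). Over the 6 relations of this kind computed, the adjusted p was 0.139, so it did not pass.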
